A study of Mus musculus with 2 samples.

How the data were processed

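Open chromatin was measured by ATAC-seq in T-helper 1 primary cells of C57BL/6NJ mice, in 1 group with 2 biological replicates. The labels give each replicate its own biosample under the same donor identifier, leave the sex as not collected and the age as unknown, and do not say whether the cells came from separate animals. The replicates are named by the replicate numbers of the labels. The deposited files used here are lists of open regions, 1 list per replicate, each derived from the alignments of that replicate alone, so replicates were compared after region calling and not before it. The build is mm10, per the labels. The aligner, the region caller and their versions are not given in the sources used here. The region names carry the words ASTARR, insert, masked, dedup and sorted and a time in hours, in addition to Th1 and the replicate number. What those words stand for is not stated. Whether the libraries are plain ATAC-seq or the insert of a reporter library therefore stays open, and the assay and the term open region follow the labels.

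Column 7 of each deposited list is a signal value, the enrichment of the region as the authors' caller gave it, and the reference it is relative to is not stated. Columns 8 and 9 hold −log10 p and −log10 q as deposited by the authors, with the smallest −log10 q at 1.01 in replicate 1 and 1.00 in replicate 2, that is a q of 0.1. Column 5 of the deposited lists is a display score, equal to the whole part of 10 times −log10 q and capped at 1000, with 1 exception in replicate 1 and 4 in replicate 2. The last column is the offset of the summit from the start of the region. These values belong to single regions of a single list. They were used to describe, rank and filter regions within each list, and a ranking was compared between the lists only over regions found in both. The number of reads behind each list is not in the deposited lists, so no counting interval for reads is given.

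Regions were checked for identical or overlapping entries within a list, and none was found. Regions on chromosomes 1 to 19, X and Y entered the comparisons. Regions on sequence without a position on a chromosome and on mitochondrial DNA were counted and left out of every comparison. A region counted as found in both replicates when it overlapped a region of the other list by at least 1 bp. Overlapping regions of both lists were then joined into 1 shared region, which took the strongest signal of each replicate. The overlap expected by position alone came from 100 circular shifts of the second list within each chromosome, and the permutation p is one-sided. Locations and genes came from the GRCm38.p6 sequence and the GENCODE M21 annotation, which have the same chromosome names and lengths as mm10. A region within 1 kb of an annotated transcript start was called a promoter region, and the others were called exonic, intronic or intergenic in that order. A gene with a shared region within 1 kb of any of its starts is said to have an open promoter.

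Before the data were examined, 21 gene lists, 27 sequence motifs, the tests and the rule for naming genes were fixed. The lists hold T helper programmes, other T cell programmes, general programmes, and markers of other cell types that the libraries could contain. 3 list members were not annotated as protein-coding and were left out. Every member of the Th1, Th2, Th17, Treg and Tfh lists could be named. From each other list the members with the highest and lowest promoter percentile, as a mean over both replicates, could be named, as could the 10 strongest promoters, genes in the densest clusters of regions (runs with gaps of at most 12.5 kb), and the regions of 9 loci. The values of 2 genes that this rule covers are not reported here. Genes named outside this rule are marked as chosen after their values were seen. The share of each list with open promoters was compared with that of all other protein-coding genes by a two-sided Fisher exact test. The number of shared regions in each gene and 20 kb on either side was compared with 10000 random lists of the same size, drawn with replacement within deciles of gene length, with a two-sided permutation p. Both were adjusted by the Benjamini-Hochberg method over the 21 lists. Promoter signal was ranked as a percentile among the protein-coding genes with an open promoter. Mean percentiles were compared by permutation between the Th1 list and the other helper lists. The mean of the T cell identity list was set beside random lists of open promoters with like CpG content. These tests treat genes as units, so their p-values do not measure the spread between animals.

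Motifs were searched on both strands in 201 bp around each summit of a region found in both replicates. A window of the same length 1 kb to a randomly drawn side served as the control. Discordant windows were compared by an exact two-sided sign test in each replicate, adjusted over the 27 motifs, and a motif was called where both replicates passed 0.05 in the same direction. The motifs are short consensus sequences, so a match does not identify the bound protein.

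The alternatives fixed beforehand were a −log10 q of at least 5, the 50000 regions of highest −log10 p, reciprocal overlap, summits inside the other list's region, promoters within 500 bp or 2.5 kb, coding transcript starts, random lists matched on the number of starts and on CpG content, gene bodies alone or with 50 kb on either side, regions outside promoters, 101 bp motif windows, base-permuted motifs, and each replicate alone. Autosomes alone, a ranking by implied pileup, and random lists matched on neighbouring genes were added after the data were seen. So were the direct comparisons of the Th1 list with the other helper lists and the sex chromosome comparisons.

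A pileup and a local background were derived from the deposited values. The signal of 31.3% of the regions of replicate 1 and 29.5% of those of replicate 2 lay on a ladder of evenly spaced values, with a −log10 p that matches a Poisson tail. Those values fit (pileup + 1) / (background + 1) with a genome-wide background of 6.22 in replicate 1 and 5.51 in replicate 2. For the other regions the same relation gave a pileup within 0.1 of a whole number in 99.95% and 99.93% of cases. This relation is an inference from the values and is not stated by the authors. It put the depth of replicate 2 at 0.886 of that of replicate 1, and it was used only where implied pileup or background is named.

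The overlap, list, motif and pileup steps were run on simulated data, and the other steps were not. The overlap step returned 15999 of 15999 planted shared regions. The test of open promoters found 85% of 200 lists of 25 genes with 97% open promoters, and called 0.5% of 4000 unchanged lists. The test of regions around genes found 95% of 20 lists of 25 genes with 2.5 times the regions, and called 1.25% of 400 unchanged lists. Its simulated region numbers were independent between genes, so windows shared by neighbouring genes were not covered. A planted motif excess of 9.86% of windows was returned as 9.99%, and 4% of 100 motif tests without a difference fell under 0.05. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.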

Results

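Chromatin accessibility was profiled, per the labels, by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in T-helper 1 cells of C57BL/6NJ mice. T-helper 1 cells are CD4 T cells that carry the transcription factor T-bet and secrete interferon-γ. The series held 1 group with 2 biological replicates and no second condition. The values therefore describe where chromatin was open in these cells and how far the replicates resembled each other. Replicate 1 had 98875 open regions of median width 593 bp (interquartile range 356 to 924), covering 70.2 Mb or 2.57% of the assembled chromosomes. Replicate 2 had 91488 regions of median width 629 bp (391 to 964), covering 68.1 Mb or 2.49%. The median signal was 6.03 (3.76 to 9.83) in replicate 1 and 6.30 (3.99 to 9.95) in replicate 2. All coordinates are mm10, and paired values give replicate 1 first.

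Most open regions were found in both replicates. Of the regions on chromosomes 1 to 19, X and Y, 86.6% of those in replicate 1 and 93.0% of those in replicate 2 overlapped a region of the other list. Together they formed 84380 shared regions. After circular shifts of the second list the overlap averaged 5.26% and 5.66%, with a highest value of 5.65% and 6.07% over 100 shifts (one-sided permutation p = 0.0099, the smallest these shifts can give). Summits of the same region lay a median of 13 bp apart, and 89.5% lay within 100 bp. Across shared regions, which are not independent replicates, the signal had a Spearman correlation of 0.963 and a Pearson correlation of 0.960 on the log2 scale. The signal differed by less than 1.5-fold in 97.8% of shared regions and by more than 2-fold in 56 of them. The overlap depended on strength. Among the weakest 10% by signal 50.8% of the regions of replicate 1 and 68.1% of those of replicate 2 were shared, and among the strongest 10% 99.98% and 100% were.

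**Figure D1:**
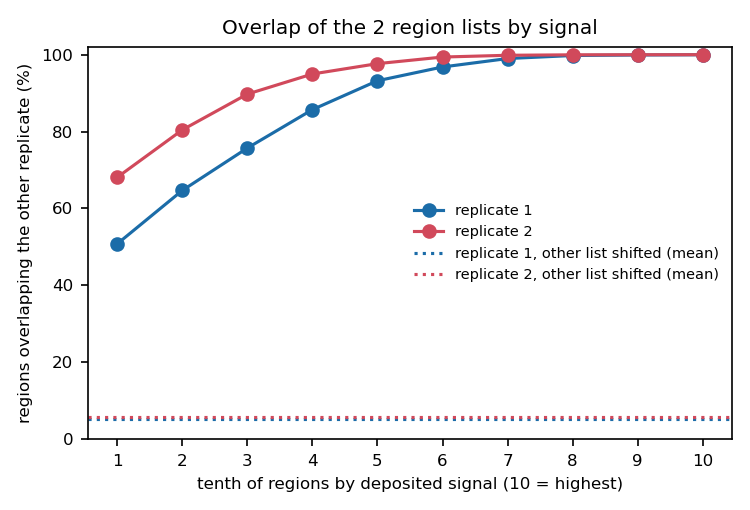
Share of regions found in the other replicate (vertical axis, percent) in 10 signal classes from weakest to strongest (horizontal axis), 1 line per replicate. The share rises from 50.8% to 99.98% in replicate 1 and from 68.1% to 100% in replicate 2.

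Open regions were concentrated at promoters. Of the shared regions, 25.5% (21538) lay within 1 kb of a transcript start, 3.02 times the 8.46% found after shifting. Exons held 8.78%, 1.21 times the shifted share, and introns 37.2%, 1.07 times. Regions between genes made up 28.5%, which was 0.577 of the shifted share of 49.4%. Promoter regions were also stronger and wider, with a median signal of 9.05 and 8.84 and a median width of 1145 bp, against 6.15 and 5.99 and 643 bp for intronic regions. An open promoter was present at 14436 of 21911 protein-coding genes (65.9%). The promoter share was 18.1% of shared regions when only coding transcript starts were counted.

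Promoters of the T-helper 1 programme were open at 29 of 30 genes (96.7%, 95% exact binomial interval 82.8 to 99.9). The set includes Tbx21, which encodes T-bet (signal 5.48 and 5.65), and Ifng, which encodes interferon-γ (7.25 and 6.55). Il12rb2, a subunit of the interleukin-12 receptor (6.58 and 6.25), and Stat4, which carries its signal to the nucleus (4.91 and 4.47), were open as well. Runx3, a partner of T-bet at Ifng, had 11 and 10.5, and the chemokine receptor gene Cxcr6 had 17.5 and 17.3. Havcr2 had 13.0 and 13.1, and the granzyme gene Gzmb, open in both replicates, had 12.4 in replicate 1. Only Ly6c2 lacked a promoter region in both replicates. The share exceeded the 65.8% of all other protein-coding genes (Fisher exact test, odds ratio 15, adjusted p = 5.24e-04 over 21 lists) and did so in all 10 alternatives, with adjusted p from 2.55e-04 to 0.00164.

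The other helper programmes had open promoters too. The follicular helper (Tfh) list was open at 16 of 16 genes (Fisher exact adjusted p = 0.00593), including Bcl6, its lineage-defining repressor, at the low signal of 2.79 and 2.74. The regulatory T cell (Treg) list was open at 18 of 20 genes (Fisher exact adjusted p = 0.0534). Foxp3, its lineage-defining factor, had a promoter signal of 11.5 and 10 in a region that is also a promoter region of Flicr and Ppp1r3f, Itgae had no promoter region, and Il10 had a region of signal 1.78 in replicate 1 only. Of the Th2 list 14 of 19 genes were open (Fisher exact adjusted p = 0.671). Gata3, the transcription factor that defines Th2 cells, had 12.7 and 12, whereas the cytokine genes Il5 and Il13 had no promoter region in either replicate, nor did Ptgdr2. Il4 and Il9 had a promoter region in replicate 1 only, with signals of 3.2 and 3.74. Of the Th17 list 13 of 17 genes were open (Fisher exact adjusted p = 0.524). Il17f (11.5 and 12.3), Rora (11.8 and 12) and Stat3 (13.4 and 14.5) were among them, and the genes without one included Il17a, which encodes the interleukin that names these cells, Il22 and Ccl20. The Il17f signal is that of a region at 20791259 to 20792083 that reaches into the 1 kb window. Among the regions of the locus it was classed as intergenic, so Il17f counts as open by that overlap. The Th1 share was not shown to differ from the Th2 share (96.7% against 73.7%, Fisher exact adjusted p = 0.101 over 4 comparisons), the Th17 share (0.101), the Treg share (0.741) or the Tfh share (1). The Treg call passed 0.05 in 7 of 10 alternatives (adjusted p from 0.0012 to 0.0896 over the 10).

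General T cell programmes were open in full. All 28 T cell identity genes (adjusted p = 1.07e-04), all 25 activation genes (2.72e-04), all 15 naive and memory genes (0.00966) and all 10 inhibitory receptor genes (0.0370) had an open promoter by the Fisher exact test. The interferon response list was open at 28 of 30 genes (Fisher exact adjusted p = 0.00227), without Gbp4 and Oas2, which are named after their values were seen. All 20 cell cycle genes (0.00161) and all 27 housekeeping genes (1.19e-04) were open. Hepatocyte markers were open at 1 of 15 genes, Apoa1 (Fisher exact adjusted p = 6.16e-05), and myeloid markers at 10 of 24 (0.0352), where Itgax (11.4 and 11.5) had the highest and Cd68 (4.33 and 4.48) the lowest mean percentile over both replicates. B cell markers were open at 9 of 18 genes (Fisher exact adjusted p = 0.261), with Cr2 (15.4 and 14.1) highest and Cd79b (2.35 and 3.53) lowest by that mean. NK cell markers were open at 6 of 15 (0.0788), with Klrb1c (18.3 and 16.1) strongest. CD8 and cytotoxic genes were open at 11 of 15 (0.786). Cd8a had no promoter region, whereas Cd8b1 had one in both replicates (7.32 and 8.14). Gzma, Gzmk and Klrc1 had one in replicate 1 only. All of these genes are named after their values were seen. Erythroid and mast cell markers (7 of 16, Fisher exact adjusted p = 0.0908), stromal and endothelial markers (9 of 20, 0.0828), neuronal markers (12 of 20, 0.671) and Hox genes (32 of 39, 0.0662) did not pass.

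Against random lists matched on the number of starts and on CpG content, the housekeeping (permutation adjusted p = 0.398), cell cycle (0.912), hepatocyte (0.0987) and myeloid (1) lists no longer stood apart. The Th17 (permutation adjusted p = 0.0393), Treg (0.0012) and CD8 and cytotoxic (0.00607) lists had more open promoters than those random lists, and the neuronal list had fewer (0.0214). Other alternatives ended the calls of the inhibitory receptor list (highest Fisher exact adjusted p = 0.247), the naive and memory list (0.0507) and the myeloid list (0.257 with replicate 1 alone). Among the 50000 regions of highest −log10 p the Hox genes had 23.1% open promoters, fewer than other genes (Fisher exact adjusted p = 1.03e-04), while within 2.5 kb of a start (0.0271) and with replicate 1 alone (0.0124) they had more, 87.2% in each. B cell markers had fewer open promoters among those 50000 regions (22.2%, Fisher exact adjusted p = 0.00649) and at a −log10 q of at least 5 (38.9%, 0.0464). So did NK cell markers within 500 bp (33.3%, 0.0295), and stromal and endothelial markers in those 50000 regions (30%, 0.0187) and with coding starts (35%, 0.0183). CD8 and cytotoxic genes had more open promoters with replicate 1 alone (93.3%, Fisher exact adjusted p = 0.0497).

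**Figure D2:**
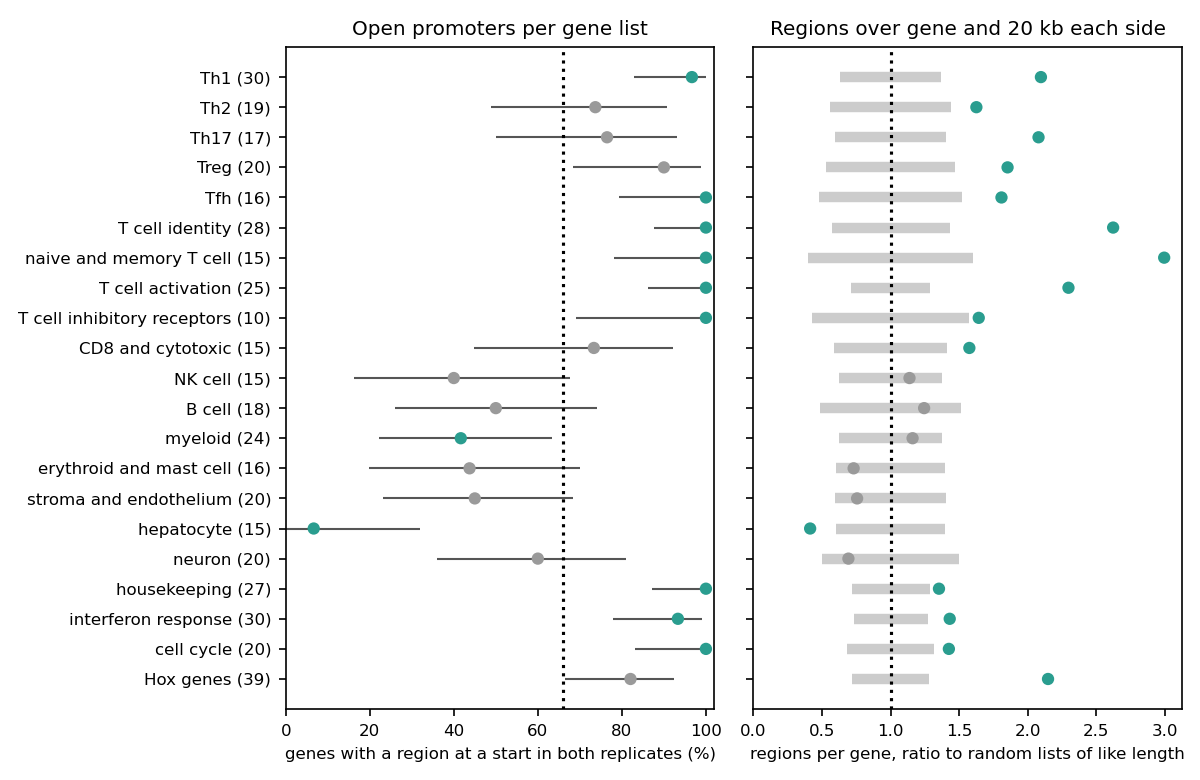
Left, percent of each of 21 gene lists with an open promoter in both replicates, with 95% exact binomial intervals as bars and a dotted line at all protein-coding genes (65.9%). Right, shared regions per gene as a ratio to length-matched random lists, with a grey bar at 1 ± 2 SD of those lists; teal marks adjusted p under 0.05, which 9 lists reach upwards on the left and 14 on the right.

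None of the 10 strongest promoters belonged to a gene of the 21 lists. The histone gene Hist1h4m led with a signal of 30.0 and 28.7, followed by 2310009B15Rik (29.1 and 28.2) and Rbm12b1 (26.3 and 24.6). Sytl3, a synaptotagmin-like gene, had 25 and 22.9, and Cacng2, a calcium channel subunit gene, had 23.8 and 23.2. By median percentile of promoter signal among open genes, the cell cycle list stood at 59.1, the housekeeping list at 39.2, the Th1 list at 24.1 and the T cell identity list at 14.8. Cd4, which encodes the co-receptor that defines this T cell class, had a promoter signal of 2.29 and 2.33 (percentile 0.267), and Tnf had 2.10 and 2.29 (percentile 0.152). Among T cell identity genes Fyn, a kinase of T cell receptor signalling, was highest with 13.2 and 13.0. No test was run on these medians or on the percentiles of single genes. The mean signal percentile of the Th1 list was 27.6. It was not shown to differ from those of the other helper lists (permutation adjusted p from 0.436 to 0.718). The mean of the T cell identity list is set beside random lists further below. All these percentiles depend on the value that is ranked. By implied pileup the medians were 70.1 for cell cycle, 69.8 for housekeeping, 42.2 for Th1 and 56.0 for T cell identity. By that value Cd4 stood at percentile 25.4 and Tnf at 41.6.

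T cell genes were surrounded by more open regions than other genes of their length. T cell identity genes had a mean of 18.3 shared regions in the gene and 20 kb on either side, 2.62 times the 6.97 of random lists (permutation adjusted p = 0.0149). Naive and memory genes had 18.1, a ratio of 3 (0.0114), with 69 regions around Bach2, a repressor that keeps T cells from differentiating. Activation genes had 10.2, a ratio of 2.30 (0.0021). Th1 genes had 8.53, a ratio of 2.10 (0.0070), with 26 at Il12rb2 and 25 at Stat4. Th17 genes had a ratio of 2.08 (0.0070), with 49 at Rora. Treg (1.85, permutation adjusted p = 0.0149), Tfh (1.81, 0.0149), Th2 (1.63, 0.0155), inhibitory receptor (1.64, 0.0462) and CD8 and cytotoxic genes (1.57, 0.0149) passed as well. Interferon response (1.43, permutation adjusted p = 0.0070), cell cycle (1.43, 0.0155), housekeeping (1.35, 0.0237) and Hox genes (2.15, 0.0021) did too. Hox genes lie side by side and their windows share regions. The same holds for neighbours in other lists, such as Il4 and Il13 in the Th2 list. The random lists draw genes independently, so the p-values of lists with neighbouring genes may be too small. Hepatocyte markers had fewer regions, a ratio of 0.414 (permutation adjusted p = 0.0070). B cell (1.24), myeloid (1.16), NK cell (1.14), erythroid and mast cell (0.731), stromal and endothelial (0.756) and neuronal markers (0.693) did not pass. The helper lists were compared by another measure, the mean percentile of each gene's region number among genes of like length. It was 81.3 for Th1, 76.6 for Th2, 75.5 for Th17, 82.3 for Treg and 76.9 for Tfh. By that measure the Th1 list did not differ from the others past the threshold (permutation adjusted p from 0.608 to 0.838).

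Counting regions in the gene body alone ended the calls of the Th2 (permutation adjusted p = 0.379), Treg (0.0891), Tfh (0.0541), inhibitory receptor (0.156), CD8 and cytotoxic (0.130), housekeeping (0.130), interferon response (0.216) and cell cycle (0.228) lists. Counting only regions outside promoters ended those of the inhibitory receptor (0.0714), hepatocyte (0.176), housekeeping (0.0906), cell cycle (0.0584) and Hox (0.0607) lists, and gave the NK cell list a call (ratio 1.70, permutation adjusted p = 0.0176). In the 50000 regions of highest −log10 p the cell cycle call ended (permutation adjusted p = 0.0804) and the Hox ratio fell to 0.799 (0.238). The inhibitory receptor call also ended on autosomes alone (0.0526) and with replicate 1 alone (0.0986).

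The Ifng locus held many open regions on both sides of the gene. From 118341046 to 118545892 on chromosome 10, the gene and 100 kb on either side held 32 shared regions and 2 regions of replicate 1 only. The strongest by signal lay beyond the gene, 54.5 kb downstream of its start (118494622 to 118495991, signal 14.1 and 13.6). By −log10 q other regions were highest. In replicate 1 it was a region at −33.9 kb (118406570 to 118407739, 259.1 against 168.7 at 54.5 kb). In replicate 2 it was the region at 29.8 kb (199.7 against 147.9 at 54.5 kb). Upstream, intergenic regions stood at −5.4 kb (118435096 to 118435967, 13.1 and 12.6), at −21.8 kb (10.5 and 10.2) and at −54.5 kb (12.3 and 12.9). Downstream, regions at 17.9 kb (11.5 and 12.7) and 29.8 kb (12.2 and 11.2) had signals above that of the promoter region (118440307 to 118441414, 7.25 and 6.55). The last 7 regions lay in introns of Ifngas1, a noncoding antisense gene next to Ifng.

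**Figure D3:**
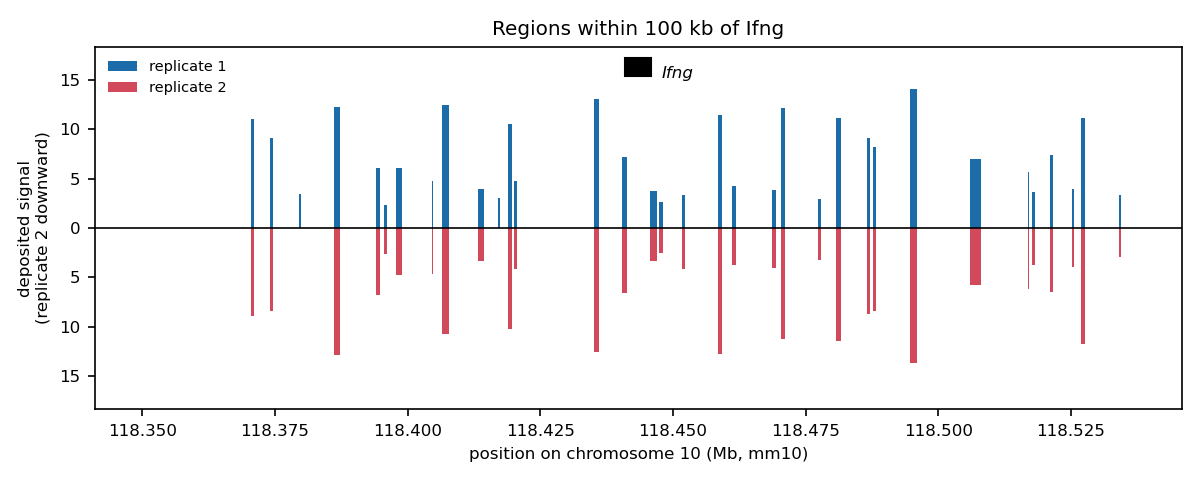
Open regions over Ifng and 100 kb on either side on chromosome 10 (mm10, horizontal axis in Mb), drawn at their width with the deposited signal as height, replicate 1 upwards and replicate 2 downwards. The 32 shared regions include those at −54.5 kb (12.3 and 12.9) and 54.5 kb (14.1 and 13.6) from the start of Ifng.

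At Tbx21 on chromosome 11 the gene and 20 kb on either side held 12 shared regions, with intergenic regions 11.7 kb upstream (97126437 to 97128210, signal 5.49 and 5.29) and 31.4 kb downstream of its start (97083005 to 97084384, 9.11 and 10.8). Il12rb2 held 26, among them intronic regions 8.9 kb downstream of its start (12.1 and 10.4) and 27.9 kb downstream (10.7 and 10.6), and a region 7.2 kb upstream (12.2 and 11.5). Cxcr3, a chemokine receptor of Th1 cells, held 3, of which the region 3.2 kb upstream (10.3 and 10.4) was stronger than the promoter (3.57 and 3.03). The Th2 cytokine locus with Il4, Il5, Il13 and Rad50 held 20 shared regions. These included a region 9.4 kb upstream of Il4 (53626821 to 53628157, 10.4 and 11.5) and introns of Rad50, which hold the known locus control region (53656485 to 53657513, 10.5 and 10.3, and 53662790 to 53663744, 9.33 and 9.12). At Il17a and Il17f on chromosome 1 the region 35.9 kb downstream of the start of Il17a (20766439 to 20767099) reached 18.9 and 17.3, and a region at 9.8 kb reached 15.4 and 15.4, although Il17a had no promoter region. Foxp3 held 6 shared regions in its window, and the strongest by signal lay in its UTR at X 7593119 to 7593804 (17.3 and 16.3). By −log10 q its promoter region was highest (315 and 209, against 132 and 118 for the UTR region). Gata3 held 11, with an intronic region 29.1 kb downstream of its start (12.2 and 12.2). At Cd4 there were 11, and an intronic region 2.8 kb downstream of its start (7.01 and 7.08) was stronger than the promoter.

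Shared regions gathered in clusters, some at T cell genes and others along stretches dense in genes. Joining neighbouring regions gave 28319 clusters, of which 12407 were single regions and 174 held more than 20. The largest held 58 regions on chromosome 2 (167675101 to 168016458) at Ptpn1, which encodes a tyrosine phosphatase, and Cebpb. Clusters of 56 regions lay at Prkch on chromosome 12 and at Cd28, Ctla4 and Icos, the genes of T cell co-stimulatory and co-inhibitory receptors, on chromosome 1 (60744187 to 61004306). A cluster of 53 regions spanned Clec16a and Socs1, an inhibitor of cytokine signalling, on chromosome 16. A stretch of chromosome 10 with 26 genes, Eef2 among them, had 51. Bach2 on chromosome 4 had 48. Stretches with many genes on chromosomes 9 and 7 had 44 each, one at Anp32e on chromosome 3 had 43, and the region of Gpr183 and Gpr18 on chromosome 14 had 42. By summed signal, a cluster at Ccr7 (35 regions) and a cluster at Irf7 (33 regions) were also among the 15 highest. No test was run on the clusters.

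Motifs of several transcription factor families were enriched at the summits of open regions. No other cell type was compared. Outside promoters the AP-1 motif, bound by Jun, Fos and BATF, was present at 25.3% and 25.2% of summits, 7.23 and 7.12 times the neighbouring windows. A composite of AP-1 and IRF sites had a ratio of 9.50 and 7.70 over all shared summits, RUNX 2.68 and 2.75, the interferon-stimulated response element (ISRE) 4.92 and 5.01, and the STAT element (GAS) 2.00 and 2.00. The T-box motif of T-bet had a ratio of 1.66 and 1.75 (exact sign test, adjusted p = 1.44e-31 and 1.06e-36), with 1.95 and 2.11 outside promoters and 0.870 and 0.818 at promoters. CTCF, an architectural protein, had 27.4 and 27.3. Promoter summits had high ratios for YY1 (51.0 and 29.6), NRF1 (36.6 and 35.4) and ETS sites (16.7 and 13.6). The shares of promoter summits were low, 0.708% and 0.688% for YY1, 0.846% and 0.823% for NRF1, and 4.01% and 4.04% for ETS. Over all shared regions only 5 and 6 control windows held a YY1 site and 14 and 13 an NRF1 site. The ratios of these 2 motifs are therefore imprecise. Of 27 motifs 15 were enriched at summits in both replicates and 4 were depleted. The enriched ones also include KLF-SP (mean ratio 4.51), C/EBP (2.63), NF-kB (2.44), E-box (1.43) and TCF-LEF (1.31). The depleted ones were GATA (0.699), HNF4 (0.691), SOX (0.644) and NFAT (0.592). Summit windows had a GC content of 50.9% and 50.8%, and the side windows 45.2% and 45.2%. REST sites passed the exact sign test in both replicates (adjusted p = 2.44e-06 and 2.24e-08) at 27 summits each, but no control window of replicate 2 held a site, so no ratio was formed and the motif is not in the count.

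With base-permuted motifs as the control, each ratio is the summit share over the mean share of all permuted forms, averaged over both replicates. The sign test instead sets each window against 1 permuted form drawn at random, and the larger adjusted p of the 2 replicates is given. NFAT turned to a ratio of 1.31 against base-permuted forms of the motif (exact sign test, adjusted p = 6.38e-13), and C/EBP (0.814) and HNF4 (1.2) lost their calls there. Against that control OCT (2.37, adjusted p = 1.67e-45), RORE (1.44, 1.76e-05) and PU.1 (3.06, 0.023) were higher by the exact sign test, and EBF (0.686), MEF2 (0.603) and p53 (0.767) were lower. Outside promoters YY1 and HNF4 (exact sign test, adjusted p = 0.0573 for each) and C/EBP (0.13) lost their calls, as did C/EBP in the narrower windows (0.079).

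**Figure D4:**
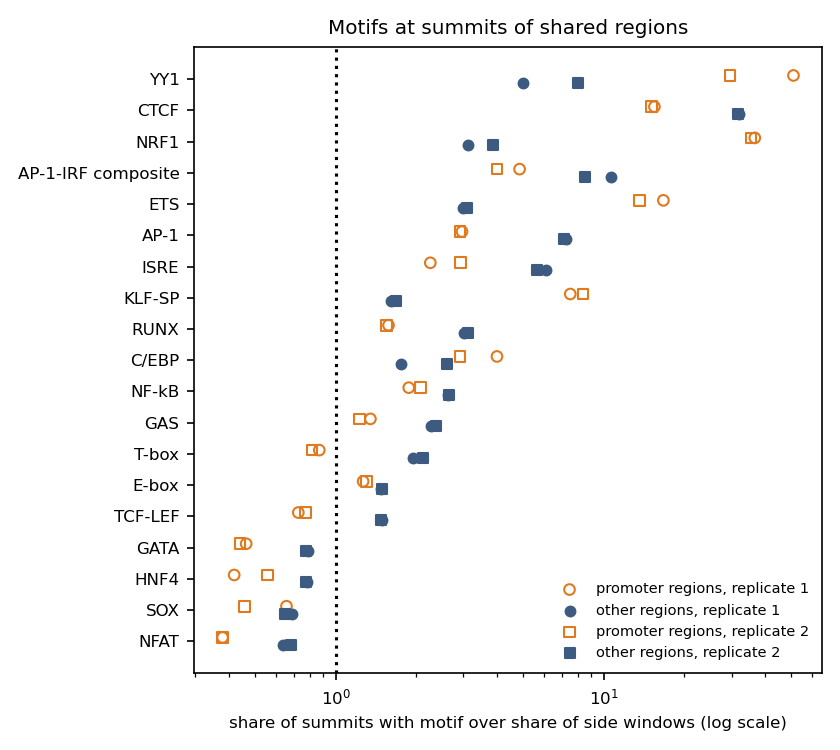
Ratio of the share of summit windows with a motif to the share of windows 1 kb to the side (horizontal log axis) for the 19 called motifs. Open orange symbols are promoter regions, filled blue symbols are other shared regions, circles are replicate 1 and squares replicate 2. CTCF lies at 15.5 and 15.1 at promoters and 31.9 and 31.8 elsewhere.

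Regions of 1 replicate only were weak and narrow. Replicate 1 had 13277 of them (13.4%) and replicate 2 had 6387 (6.99%). Their median signal was 3.05 and 2.99, against 6.82 and 6.66 for shared regions, and their median width 264 and 287 bp, against 664 and 663 bp. Promoters made up 11.5% and 11.6% of them, against 25.3% and 25.3%, and ETS sites were at 0.286% and 0.188% of their summits, against 1.35% and 1.36%. CTCF sites were at 2.92% and 2.82%, against 4.17% and 4.14%, RUNX sites at 3.56% and 3.04%, against 4.16% and 4.14%, and AP-1 sites at 17.7% and 19%, against 21.4% and 21.2%. T-box sites were at 2.14% and 1.5%, against 1.61% and 1.60%. A few were strong. In replicate 1, 3 of the 5 strongest lay on the Y chromosome, at 258212 to 263602 (signal 19.6), at the promoter of Eif2s3y (14.5) and at the promoter of Ddx3y (11.9). In replicate 2, 3 of the 5 strongest lay on the X chromosome, the first at 50549426 to 50550719 (11.6). No test was run.

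The sex chromosomes had few open regions. The autosomes had 39.3 and 36.3 regions per Mb, from 30.4 on chromosome 14 to 58.1 on chromosome 11 in replicate 1 and from 28.2 to 54.1 in replicate 2. The X chromosome had 12 and 11.8 per Mb. The Y chromosome had 18 regions in replicate 1 and 11 in replicate 2. Of these, 10 in replicate 1 and 0 in replicate 2 lay in the first 10 Mb, and the lowest Y region of replicate 2 started at 90738897.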

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

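No test was run in this part. Regions were called on sequence without a position on a chromosome, part of it assigned to chromosomes 4 and X, 87 in replicate 1 on 16 sequences and 83 in replicate 2 on 17 sequences. They are listed here because no comparison of the report uses them and their number is above 0. The sequence JH584304 held 28 of them in replicate 1 and 26 in replicate 2. A further 2 regions in each replicate lay on mitochondrial DNA. No explanation was tested for these regions, technical or biological.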

How the results depend on the processing

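Autosomes alone, the ranking by implied pileup and the matching on neighbouring genes were chosen only after the data were seen, and all other alternatives here were fixed beforehand. Of the main results, 90 values under an alternative stayed on the same side or within their error and 23 moved. Of the values of single lists, genes and motifs, 1198 stayed, 450 moved without a test, 24 gained a call, 32 lost a call and 8 turned. The share of regions found in 1 replicate only was 11.1% in replicate 1 and 5.64% in replicate 2 at a −log10 q of at least 5, and 19% and 12.4% with reciprocal overlap. Signal agreement across shared regions had a Spearman correlation of 0.960 at that −log10 q, 0.960 for the top 50000 regions, 0.964 with reciprocal overlap and 0.971 with −log10 p in place of signal, each outside the narrow interval of the main value. The promoter share of regions was 26.3% at the stricter −log10 q, 34.0% in the top 50000, 22.4% within 500 bp, 34.5% within 2.5 kb, 18.1% with coding starts, and 23.4% to 24.3% when 1 replicate was left out. The number of lists with fewer open promoters, 2 as reported, was 5 in the top 50000 regions and 1 with reciprocal overlap, within 2.5 kb, against matched random lists, and with either replicate left out. Lists with more regions around their genes numbered 6 for gene bodies alone, and lists with fewer numbered 0 outside promoters. In the top 50000 regions the Hox genes turned, with 23.1% open promoters (Fisher exact adjusted p = 1.03e-04; 1.03e-04 to 1 over its alternatives) and a ratio of 0.799 for regions around them (permutation adjusted p = 0.238; 0.0014 to 0.238). Myeloid markers lay above their matched random lists at 41.7% (permutation adjusted p = 1; 0.0191 to 1 over its alternatives). Against base-permuted motifs, NFAT turned to 1.31, C/EBP to 0.814, HNF4 to 1.2, OCT to 2.37 and RORE to 1.44. The stricter settings leave fewer regions, and the cause of these changes was not tested. Counting deposited entries one by one changed nothing, since no list holds overlapping entries.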

Other observations

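The test for cells of other types, the ranking by implied pileup, the neighbour matching, the 10 Mb limit on the Y chromosome and the comparisons of X promoters and of Firre were chosen only after the result was seen. Interferon response genes were open with a wide range of strength. Stat2, a subunit of the factor that type I interferon activates, had a promoter signal of 16.8 and 16.6, and Ifit1 had 16.8 and 15.7, while Oas1a (3.60 and 3.84) and Isg15 (3.83 and 4.14) were lowest by mean percentile over both replicates. Their median percentile was 34.4 by signal and 46.1 by implied pileup. Of the cell cycle genes, the cyclin gene Ccna2 (16.1 and 15.4) and the kinase gene Aurka (16.2 and 14.3) were highest by that mean, and Aurkb (4.56 and 4.85) was lowest.

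Hox genes, which pattern the body axis, had many weak regions. The list had 7.23 shared regions per gene, 2.15 times random lists of like length, and a median promoter percentile of 7.71 by signal and 9.11 by implied pileup. Hox genes lie side by side, so the same regions count for several of them, and the random lists do not share this. The excess outside promoters was 1.39 (permutation adjusted p = 0.0607). Hoxb8 was lowest by mean percentile, with a signal of 2.16 and 2.42, and Hoxa4 had 12.9 and 11.7. Among erythroid genes Klf1, an erythroid transcription factor gene, had a promoter signal of 14.9 and 15.8.

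The sex chromosomes separated the replicates. In replicate 1 the Y genes Kdm5d (signal 5.12), Eif2s3y (14.5), Uty (10.8) and Ddx3y (11.9) had a region at their promoter, and in replicate 2 none of the 4 did. In replicate 2 the start of Xist, the noncoding RNA that silences 1 X chromosome in females, had 2 regions (7.32 at the stronger), and in replicate 1 it had none. Further inside the gene a region found in both replicates reached 9.69 in replicate 1. Firre, a noncoding gene of the X chromosome at 50555744 to 50635321, held 3 regions in replicate 1 and 21 in replicate 2, of which 17 were in replicate 2 only. The implied promoter pileup per depth was higher in replicate 2 than in replicate 1 by 1.71 at Kdm6a, 1.70 at Kdm5c and 1.67 at Eif2s3x, genes known to escape X inactivation, and by 1.09 at Ddx3x, against a middle 95% of 0.768 to 1.2 over all open promoters. Among X genes 5 of 420 open promoters exceeded 1.5, and among autosomal genes 28 of 14016 did. In the other direction 4 X genes and 79 autosomal genes differed as much, and the median ratio was 0.971 on the X chromosome and 0.966 on the autosomes.

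Male-specific Y regions in replicate 1 alone cannot be put down to the lower depth of replicate 2, because the 10 regions would keep a median −log10 p of 67.0 at that depth and all 10 would stay above 10. Cells from animals of different sex may account for them, since the Xist start had an implied pileup of 192 in replicate 2 and no region in replicate 1, a test that could have come out otherwise. The labels leave the sex as not collected and put both biosamples under the same donor identifier, so this stays a hypothesis. Masking of sequence that differed between the replicates was not tested, and apart from a difference of sex no biological explanation was.

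T cell identity genes had low promoter signals, with a median percentile of 14.8. By implied pileup their median was 56.0. Their median implied background was 9.84 and 9.94 times that of the genome, against 4.60 and 4.48 for all open promoters. A local background in the deposited signal is therefore a candidate explanation. Each value is the highest over the regions at a gene's starts. At genes with several such regions, the background can belong to another region than the one whose signal was ranked. CpG content alone does not account for the low signal. The mean signal percentile of 19.8 lay below the 30.3 to 50.6 of random lists of open promoters with like CpG content. By implied pileup the mean of 53.5 lay above their 28.1 to 46.3. The random lists had a mean signal percentile of 40.4, and the median of all open promoters was 50.1, so a part played by CpG content stays open. A large share of B cells or myeloid cells would raise regions around their markers, yet these had a ratio of 1.24 and 1.16 against 2.62 for T cell identity genes, while NK cell markers outside promoters (1.70) and CD8 and cytotoxic genes (1.57) leave such cells open. No biological explanation was tested.

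T cell identity genes also had the high number of regions described above, and gene density is the technical explanation that was tested. Random lists matched on length and on neighbouring genes had a mean of 6.78 regions (middle 95% 4.68 to 9.32) against 18.3 for the list, so the density of genes does not account for it. The Th1 list, with 8.53 against 3.64 (2.5 to 4.93), behaved likewise. Many regulatory elements around the genes that define a cell would be in line with a ratio of 2.70, which is a hypothesis and was not tested against other cell types.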
